A study of Mus musculus with 96 samples.

How the data were processed

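Liver RNA was sequenced from 48 male F1 mice of reciprocal crosses between the strains NOD/ShiLtJ and PWK/PhJ. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with Trizol, and poly-A selected, unstranded TruSeq libraries were read as 68 bp single-end reads. Each mouse was run on 2 flowcells, which gives 96 entries in the labels, and the deposited tables hold 1 column per mouse. How the runs were joined is not given in the sources used here.

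The deposited values are expected counts, which are estimated counts per gene that need not be whole, given separately for the NOD and the PWK allele and not scaled to depth. They are named as EMASE output, a method that shares out reads between the alleles of an F1 animal. CASAVA 1.7.0, Bowtie 1.1.2 and the builds GRCm38 and mm10 are named in the submitters' processing notes. The EMASE version, the gene annotation and the filters of the submitters are not given in the sources used here. Of 38924 Ensembl genes in the tables, 37607 were matched by identifier to the GENCODE M21 annotation of GRCm38 for symbols and coordinates, and the other 1317 held 0.16% of the counts.

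Total expression was the sum of the NOD and PWK expected counts of a gene, rounded to whole numbers. Genes were kept by edgeR's filterByExpr, which left 11979 genes, and libraries were scaled with TMM. A negative binomial model with 8 group means was fitted to all 48 mice with edgeR 4.0.16 in R 4.3.3, and each contrast was tested with its robust quasi-likelihood test (two-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Main effects of age, diet and cross compare 24 mice with 24 mice, and interactions and the diet effect at each age came from the same fit. The biological coefficient of variation of this fit was 16.6%.

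Allelic expression was tested with the NOD and PWK expected counts of a mouse as 2 columns of the same library size, with the mouse as a fixed effect and a PWK over NOD coefficient per group. Autosomal genes with a mean count of at least 20 per mouse were kept, which left 9362 genes. The allele effect is the mean log2 ratio of PWK over NOD. The parent-of-origin effect is the maternal over paternal log2 ratio, from the difference between the reciprocal crosses, with the strain written first taken as the dam. Males carry 1 X chromosome, from the dam, so X-linked counts given to the other strain are counts given to the wrong allele.

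Gene lists and cell type marker lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The lists, the tests, the first set of alternatives below and the rule for naming genes were fixed before the data were examined. That rule names, among genes past the threshold with a mean of at least 2 CPM and the same sign in at least 5 of the 6 lane sets, the 8 with the largest rise and the 8 with the largest fall. It adds up to 4 members of each list by p-value, the imprinted and sex-linked check genes, and up to 4 genes per interaction. It leaves out predicted genes without a proper symbol. Some genes that the rule names are not reported here. Genes called for the diet in older mice and for age or diet on the allele ratio were taken from the same lists or by smallest p-value after the results were seen.

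Each flowcell lane held 1 mouse of every group, so the replicate number marks a shared lane set. Deviations of mice from their group means had a mean correlation of -0.005 within a lane set and of 0.001 between mice of different lane sets and groups. Of 168 pairs within a lane set, 32 had a correlation above 0.1, and 8 of 48 mice correlated best with a mouse of their own lane set. Counts of the 120 pairs of mice within groups differed by 4.62 to 57.7 chi-square units per gene, so no pair was as close as sampling noise.

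Alternatives were DESeq2 1.42.0, RLE size factors, other low-count filters, the lane set as a block, counts not rounded, each lane set left out in turn, the mice labelled 25 left out, and for alleles limma on log2 ratios and scaling of each allele column. Added after the data were seen were fits without the 6 mice of the shallowest barcode, without 10 mice with pancreas transcripts, and with a clock gene score or a haemoglobin score per mouse as a covariate. The clock score is the mean log2 CPM of 6 genes (Dbp, Tef, Per2, Per3, Ciart and Nr1d2) minus that of 4 genes (Arntl, Npas2, Clock and Nfil3). CPM values on a log2 scale had a pseudocount of 0.5.

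On data simulated for the age comparison over 11979 genes, the test recovered 70% of 50 genes changed by 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 4 of 11779 unchanged genes. Each gene was drawn independently there. Variation that many genes of a mouse share, as reported below, was thus not part of this check, and false calls may be more frequent in the real data. On 2000 genes simulated for the allele effect, it recovered 84% of 25 genes at a ratio of 1.19 and 100% at ratios from 1.41, and called 3 of 1900 unchanged genes. For the parent-of-origin effect it called 6 of 1900 unchanged genes. Sequence shared between genes was measured as the share of 68-base windows of a gene's exons found in other annotated genes. Of 318 named genes, 25 shared at least 50% of their windows and 80 at least 10%. Values of such genes depend on how reads were divided between copies, and the unstranded libraries do not separate overlapping genes. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.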

Results

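Liver messenger RNA was measured in 48 male F1 mice from reciprocal crosses of NOD/ShiLtJ, an inbred strain prone to autoimmune diabetes, with PWK/PhJ, an inbred strain derived from wild mice. The strain written first in a cross (NODxPWK or PWKxNOD) was taken as the dam. Mice were fed 0.009 g/kg (normal) or 0.050 g/kg (high) of cholecalciferol, which is vitamin D3. They were sampled at a younger or an older age, giving 8 groups of 6 mice. The age labels read 8 for the younger and 24 or 25 for the older mice without a unit, while the protocol names 15 and 24 weeks. Ages are therefore given only as younger and older. Label 25 was carried by 7 mice, all of them older mice on the normal diet (5 NODxPWK and 2 PWKxNOD). Each value below is a log2 difference ± its standard error over 24 mice against 24 mice unless stated otherwise. Adjusted p-values are those of edgeR's quasi-likelihood test, and coordinates refer to GRCm38. Summed expected counts ranged from 2.03 to 7.48 M per mouse (M for mega, median 5.27 M), and the 6 mice of 1 barcode held 2.03 to 3.09 M.

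**Figure D1:**
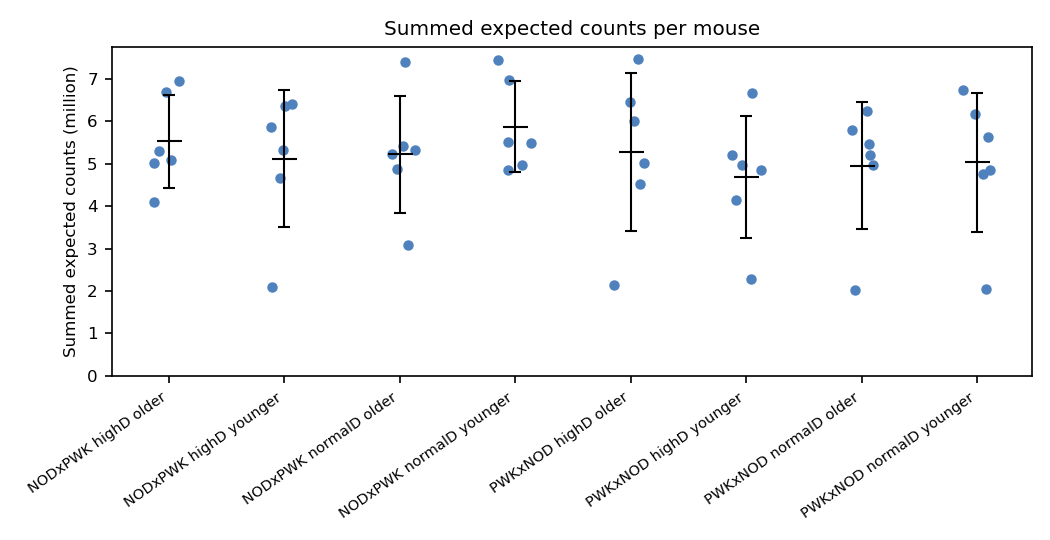
Summed expected counts in M (mega) per mouse (vertical axis) for the 8 groups of 6 mice, with bars at the mean and its SD. The totals span 2.03 to 7.48 M, and all groups overlap.

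The age comparison shows how the liver transcriptome of older mice differed from that of younger mice. The highest rises were those of Saa2 and Saa1, which encode serum amyloid A apolipoproteins of the acute phase, at 4.39 ± 0.37 and 3.95 ± 0.30 (adjusted p = 6.13e-12 and 2.86e-13). Orm2, an orosomucoid gene, rose by 3.09 ± 0.19 (adjusted p = 2.22e-16). Among the falls were those of Sult2a1, a hydroxysteroid sulfotransferase, at -2.76 ± 0.46 (adjusted p = 2.67e-05), and of Cyp17a1, a steroid hydroxylase, at -1.53 ± 0.21 (adjusted p = 5.42e-07). Orm2 (ENSMUSG00000061540, chromosome 4, 63362449 to 63365878) averaged 16.4 ± 8.78 CPM (SD, n = 24) in older and 1.91 ± 0.789 CPM in younger mice. Sult2a1 (ENSMUSG00000078798, chromosome 7, 13796246 to 13837409) averaged 1.03 ± 2.01 CPM in older and 6.06 ± 8.35 CPM in younger mice. Over both ages it lay near the floor in NODxPWK mice (0.687 ± 0.834 CPM, against 6.41 ± 8.32 CPM in PWKxNOD mice). Its highest values were those of younger PWKxNOD mice. Dnase1, an endonuclease gene, rose by 2.08 ± 0.16 and Dkk4, which encodes a Wnt antagonist, by 2.05 ± 0.20. The monooxygenase gene Moxd1 rose by 2.02 ± 0.45, the potassium channel gene Kcnk1 by 1.86 ± 0.27 and Lcn2, which encodes a siderophore-binding lipocalin, by 1.83 ± 0.38. Lower values in older mice were found for Nt5e, an ecto-nucleotidase (-1.57 ± 0.16), Nipal1, a magnesium transporter gene (-1.44 ± 0.31), Cyp2c38 (-1.42 ± 0.24) and Cyp2c39 (-1.40 ± 0.24). Eif4ebp3 was also lower (-1.73 ± 0.23), but 64.5% of its windows occur in other genes. Saa1, Saa2, Orm2 and Sult2a1 share 16.8 to 22.8% of their windows with relatives, so that their separate values are uncertain.

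Acute phase genes rose as a group with age. Of 24 tested members, 11 rose (12 when adjusted over the list alone), among them Hp (0.81 ± 0.06) and Hpx (0.59 ± 0.04), which encode haptoglobin and hemopexin. The list passed the set test (adjusted p = 2.41e-19, and adjusted p = 0.021 with an estimated correlation). Markers of bile duct epithelium rose alongside it: Spp1 (0.72 ± 0.08) and Sox9 (0.83 ± 0.14) were 2 of 4 tested members called, also over the list alone. Their list adjusted p was 0.00167 (adjusted p = 0.044 with an estimated correlation). The immunoglobulin light chain gene Igkc rose by 0.82 ± 0.16. Exocrine pancreas markers differed by a median of 1.44 between ages and did not pass as a list (adjusted p = 0.107).

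**Figure D2:**
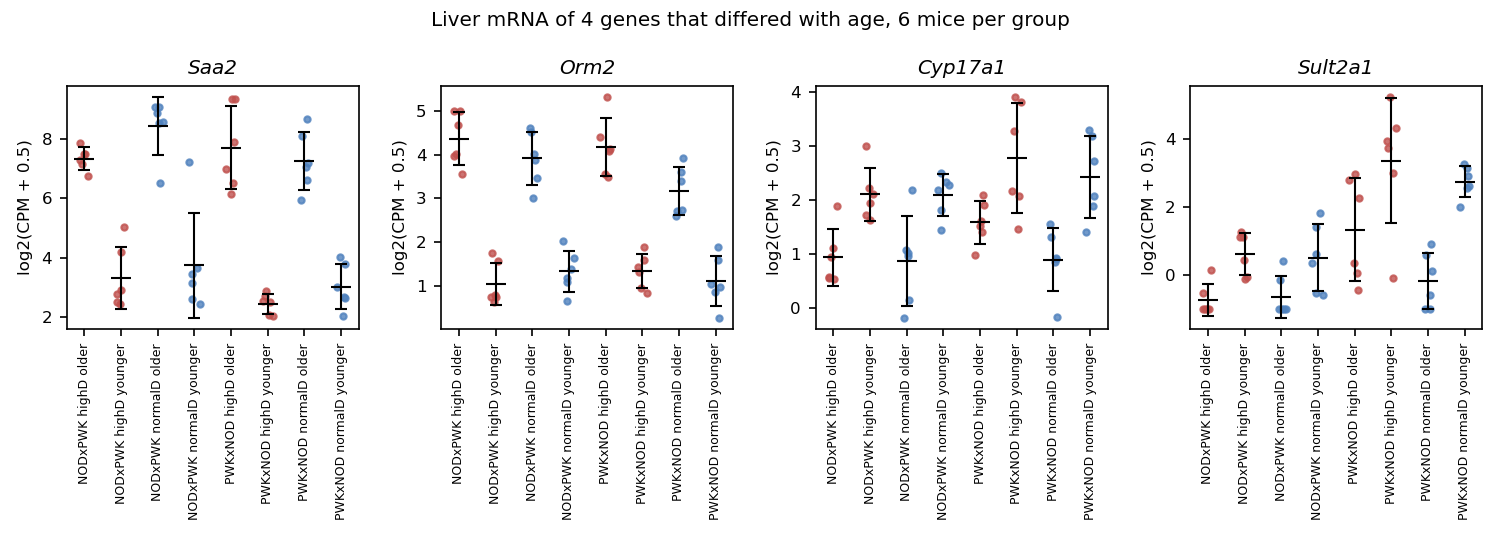
Expression of Saa2, Orm2, Cyp17a1 and Sult2a1 as log2(CPM + 0.5) on the vertical axis in the 8 groups, with 1 point per mouse (red for high, blue for normal vitamin D), and bars at the mean and SD of 6 mice. Saa2 and Orm2 were higher in older mice by 4.39 and 3.09, and Cyp17a1 and Sult2a1 differed by -1.53 and -2.76.

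Averaged over both diets, genes of drug metabolism and fatty acid oxidation were higher in older mice, and genes of fatty acid synthesis lower. Both rises were seen mainly on the normal diet. In NODxPWK mice mean xenobiotic levels in log2 CPM were 6.669 to 7.175 in older and 6.296 to 6.621 in younger normal diet mice. With high vitamin D they were 6.615 to 6.839 and 6.438 to 6.923. Of the NODxPWK normal older mice, those labelled 25 had 6.844 to 7.175 and the other 6.669. In PWKxNOD mice the ages overlapped at both diets. Of 25 xenobiotic metabolism genes 12 rose (14 adjusted over the list alone), with Aldh1a1 at 0.69 ± 0.07, Ephx1 at 0.51 ± 0.06 and Cyp2c50 at 0.61 ± 0.09. The list passed the set test (adjusted p = 2.67e-10, but adjusted p = 0.0933 with an estimated correlation). Of 24 fatty acid oxidation genes 11 rose (15 over the list alone), including the acyl-CoA dehydrogenase genes Acadm (0.36 ± 0.05) and Acadvl (0.18 ± 0.03). This list had an adjusted p = 1e-08 (adjusted p = 0.172 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis 9 fell (11 over the list alone), with Scd1, a desaturase gene, at -1.03 ± 0.20 and the lipogenic regulator Thrsp at -0.96 ± 0.19. As a list they were lower (adjusted p = 7.02e-07, adjusted p = 0.233 with an estimated correlation). Of 18 glucose metabolism genes 8 fell and 1 rose (13 and 1 over the list alone), among them Igfbp1 (-1.03 ± 0.18) and Pfkfb1 (-0.63 ± 0.12). The set test gave an adjusted p = 6.1e-06 (adjusted p = 0.0933 with an estimated correlation). The 25 genes of cholesterol synthesis and uptake were shifted down (adjusted p = 6.41e-06, adjusted p = 0.501 with an estimated correlation), and 2 of them passed the test, among them Stard4 (-0.41 ± 0.08). Cyp3a11 rose by 0.60 ± 0.09, as 1 of 12 tested genes of vitamin D metabolism and action, a list that did not move as a whole (adjusted p = 0.486). Of 21 bile acid genes, Hsd3b7 (0.26 ± 0.04) and Amacr (0.33 ± 0.06) rose and the uptake transporter gene Slc10a1 fell (-0.29 ± 0.05), with no shift of the list (adjusted p = 0.195).

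Sex-biased, clock and stress genes also differed with age. Of 9 tested genes with female-biased liver expression 5 fell (6 over the list alone), including Cyp2a4 (-1.26 ± 0.17), Cyp17a1 and Sult2a1. Together they were lower (list adjusted p = 2.42e-06, adjusted p = 0.0592 with an estimated correlation). Of 19 male-biased genes 5 rose (5 rose and 2 fell over the list alone), with Susd4 at 1.18 ± 0.09 and Cspg5 at 0.83 ± 0.13. The male-biased list had an adjusted p = 0.0501 (0.0485 with the lane set as a block, and adjusted p = 0.526 with an estimated correlation). Of 19 clock genes and their outputs 9 fell and 1 rose (10 and 3 over the list alone), with the clock output gene Dbp at -1.30 ± 0.23, Per3 at -0.96 ± 0.18 and Nfil3 at 0.54 ± 0.10. Clock genes as a list were shifted down (adjusted p = 0.0012, adjusted p = 0.0997 with an estimated correlation). The shift was uneven over the groups: the mean clock score in older and younger mice was -0.32 and 1.14 (high) and -1.45 and 1.19 (normal) in NODxPWK, and 3.31 and 3.37 (high) and 1.67 and 2.45 (normal) in PWKxNOD. Of the 19 genes only Cry1 passed the test for age by cross (adjusted p = 0.0227; 0.109 for Dbp). Of 19 genes of the stress and unfolded protein response 7 fell and 1 rose (8 and 3 over the list alone), among them the chaperone genes Hspa5 (-0.61 ± 0.07) and Creld2 (-1.18 ± 0.16). Their list adjusted p was 0.0012 (adjusted p = 0.2 with an estimated correlation). In the growth hormone and IGF axis, Socs2 (-1.10 ± 0.23) and Igf1 (-0.27 ± 0.05) fell and Igfbp2 rose (0.44 ± 0.10), among 2 rises and 3 falls in 14 genes, with the same numbers over the list alone. Among 19 antigen presentation genes, H2-D1 (0.26 ± 0.04), H2-K1 (0.19 ± 0.05) and B2m (0.16 ± 0.05) rose, with 5 rises over the list alone. Among 15 hepatocyte markers 3 rose and 4 fell (3 and 5 over the list alone), with the urea cycle genes Cps1 at -0.42 ± 0.07 and Ass1 at -0.42 ± 0.08. The extracellular matrix list was lower (adjusted p = 0.0346, adjusted p = 0.526 with an estimated correlation), with Sparc (-0.26 ± 0.07) and Col4a1 (-0.22 ± 0.07) called among 19 genes.

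In total 1439 of 11979 genes differed with age, 769 higher and 670 lower in older mice, of which 68 changed at least 2-fold, and DESeq2 called 1510. Without the 7 mice labelled 25 the count was 778 and Lcn2 stood at -0.50. With a clock gene score as a covariate it was 740 (674 to 1336 with scores permuted within groups, median 780.5). Without 10 mice with pancreas transcripts the count was 904 (776 to 1142 in 30 random removals of as many mice per group, median 953.5). Both counts lay within these ranges.

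The diet comparison shows the response to high vitamin D. Averaged over both ages and crosses, the largest rise was that of Dio1, which encodes the iodothyronine deiodinase that activates thyroid hormone, at 1.24 ± 0.20 (adjusted p = 0.00142). Dio1 (ENSMUSG00000034785, chromosome 4, 107291465 to 107307169) averaged 38.9 ± 20.6 CPM (SD, n = 24) with high and 18.8 ± 16.7 CPM with normal vitamin D. Nrg4, a neuregulin gene, rose by 0.64 ± 0.15, the organic anion transporter gene Slc22a7 by 0.58 ± 0.14, Mroh2a by 0.38 ± 0.09, Ginm1 by 0.38 ± 0.06 (adjusted p = 0.000626) and the kinase gene Nuak2 by 0.38 ± 0.09. Ces2c (0.49 ± 0.10) and Mup11 (0.57 ± 0.14) rose as well, with 25.8% and 74.6% of their windows shared with relatives. Values were lower for Clpx, a subunit of a mitochondrial protease (-0.47 ± 0.10, adjusted p = 0.0173), Oat, ornithine aminotransferase (-0.45 ± 0.11), Tm6sf2, which acts in lipoprotein secretion (-0.43 ± 0.10) and Csad, an enzyme of taurine synthesis (-0.40 ± 0.09). Lower values were also found for St5 (-0.39 ± 0.09), Slc17a8 (-0.38 ± 0.09), Ndrg1 (-0.37 ± 0.09), Hacl1 (-0.37 ± 0.08) and Ephx1, microsomal epoxide hydrolase (-0.30 ± 0.06).

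The 12 tested genes of vitamin D metabolism and action did not move as a list with the diet (median -0.02, adjusted p = 0.646) and none of them was called by edgeR. Stellate cell markers were lower as a list (median -0.32, adjusted p = 0.00737), as were extracellular matrix genes (adjusted p = 0.0207), fatty acid oxidation genes (adjusted p = 0.0388) and glucose genes (adjusted p = 0.0388). Antigen presentation genes (adjusted p = 0.0207) and male-biased genes (adjusted p = 0.0388) were shifted up. These list calls rest on small shifts without called members, and each was lost with an estimated correlation (adjusted p = 0.805 with an estimated correlation for fatty acid oxidation and adjusted p = 0.731 for the other lists). Stellate and matrix genes also ran opposite to haemoglobin transcripts between mice of the same group (r = -0.881 and -0.8), and whether their shift with the diet follows that relation was not tested. Over the list alone, 3 fatty acid oxidation genes fell, and 3 male-biased genes rose and 1 fell.

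In total 41 genes differed with the diet (21 higher, 20 lower with high vitamin D), 1323 genes had an unadjusted p of at most 0.05, and DESeq2 called 111. The edgeR count ranged from 6 without lane set 3 to 43 without lane set 5, and was 0 without the 7 mice labelled 25 (976 genes at the unadjusted threshold), without the 10 mice with pancreas transcripts (1029) and with a clock score as a covariate (849).

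The diet response differed between ages. In older mice (12 against 12) Cyp4a10 and Cyp4a14, fatty acid omega-hydroxylases regulated by PPAR alpha, were lower with high vitamin D at -2.39 ± 0.42 and -2.35 ± 0.52 (adjusted p = 0.000714 and 0.00541). Their values in younger mice were 0.68 ± 0.41 and 1.18 ± 0.69, and the difference between ages passed the test (interaction adjusted p = 0.00919 and 0.0447). Of 24 fatty acid oxidation genes 6 fell in older mice (7 over the list alone), among them the thioesterase gene Acot1 (-1.63 ± 0.31) and Ehhadh (-0.67 ± 0.12). For this list adjusted p = 6.79e-07 (adjusted p = 0.507 with an estimated correlation). Of 25 xenobiotic metabolism genes 8 fell (10 fell and 1 rose over the list alone), including Ephx1 (-0.57 ± 0.09), Gstm1 (-0.53 ± 0.12) and Cyp2b10 (-0.83 ± 0.24, against 1.02 ± 0.24 in younger mice). The xenobiotic list was lower at an adjusted p = 0.000407 (adjusted p = 0.507 with an estimated correlation). In mean log2 CPM of this list, normal older mice labelled 25 all lay above the high diet older mice of their cross. These were 6.844 to 7.175 against 6.615 to 6.839 in NODxPWK, and 7.494 and 7.799 against 6.499 to 7.331 in PWKxNOD. Those labelled 24 lay within the high diet range (6.669 in NODxPWK, 6.499 to 6.921 in PWKxNOD). Label and diet cannot be told apart for this list. Of 19 male-biased liver genes 8 rose and 1 fell (11 and 1 over the list alone), with Hsd3b5 at 0.45 ± 0.09, Serpina12 at 0.99 ± 0.21, Cyp7b1 at 0.55 ± 0.13 and Elovl3 at -0.72 ± 0.21. As a list the male-biased genes were higher (adjusted p = 8.54e-09, adjusted p = 0.164 with an estimated correlation). Scd1 was lower at -1.36 ± 0.29 and Igfbp1 at -1.34 ± 0.26, the latter as 1 of 18 glucose genes. Over the list alone 6 of these fell and 1 rose (list adjusted p = 0.0119, adjusted p = 0.507 with an estimated correlation). Clock genes moved in both directions, with Dbp at 1.44 ± 0.34, Bhlhe41 at 1.31 ± 0.33 and Per3 at 1.03 ± 0.27 higher, and Arntl at -1.16 ± 0.28 and Nfil3 at -0.62 ± 0.14 lower. The 19 clock genes did not shift as a list (5 up and 5 down over the list alone, adjusted p = 0.434). The heat shock genes Hspa8 (-0.42 ± 0.11) and Hsph1 (-0.59 ± 0.17) fell among 19 stress genes (6 over the list alone; list adjusted p = 0.00462, adjusted p = 0.507 with an estimated correlation). Spp1 rose by 0.53 ± 0.10. Stellate markers had a median of -0.36 (adjusted p = 0.0553, 0.0392 with the lane set as a block, and adjusted p = 0.836 with an estimated correlation). Mitochondrial check genes had a median of 0.10 (adjusted p = 0.0312, adjusted p = 0.836 with an estimated correlation) and pancreas markers a median of -1.54 (adjusted p = 0.202).

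**Figure D3:**
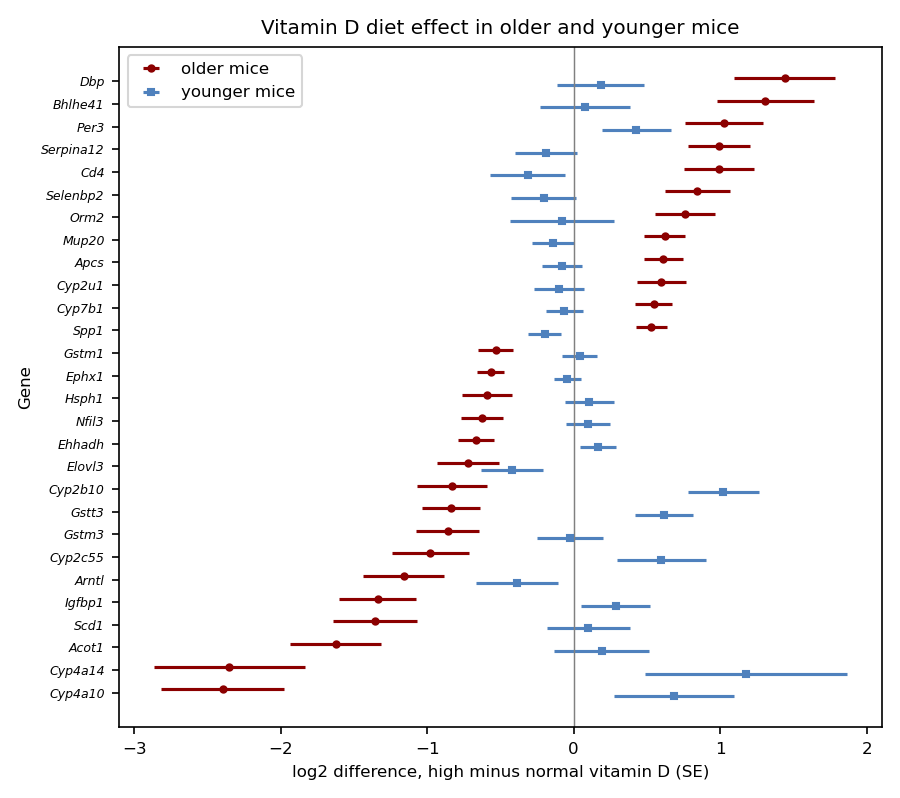
Log2 difference between high and normal vitamin D (horizontal axis, with SE) for 28 genes called in older mice, in older mice (circles) and younger mice (squares), 12 mice per diet and age. Cyp4a10 and Cyp4a14 stood at -2.39 and -2.35 in older and at 0.68 and 1.18 in younger mice.

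In older mice 445 genes differed with the diet (228 higher, 217 lower; 521 by DESeq2), and in younger mice edgeR called 0 genes, with 573 genes at the unadjusted threshold and 10 called by DESeq2. The interaction of diet and age was called for 74 genes (33 positive and 41 negative for older minus younger; 158 by DESeq2). Its smallest p-values belonged to Cyp4v3 (0.84 ± 0.15), Gnat1 (1.245 ± 0.23), Cyp2b10 (-1.85 ± 0.34) and Scmh1 (0.83 ± 0.16), each at an adjusted p = 0.00919. Male-biased genes were shifted by the interaction as a list, with 3 called (11 over the list alone; adjusted p = 6.29e-13, adjusted p = 0.0293 with an estimated correlation). Fatty acid oxidation genes were shifted the other way, with 5 called (9 over the list alone; adjusted p = 1.39e-09, but adjusted p = 0.25 with an estimated correlation). Pancreas markers moved with the same interaction (median -3.61, adjusted p = 0.015, adjusted p = 0.771 with an estimated correlation). The count of 445 genes in older mice fell to 6 without the mice labelled 25, 18 without the mice with pancreas transcripts and 53 with a clock score as a covariate. The count of 74 interaction genes fell to 0 (1033 at the unadjusted threshold), 0 (857) and 11. The first 2 of these removals are not separate checks. Older normal diet mice with both label 25 and pancreas transcripts were NODxPWK replicates 1, 2 and 5 and PWKxNOD replicate 2. Leaving out lane sets gave 171 (without lane set 6) to 439 genes (without lane set 4) for older mice and 4 (without lane set 1) to 88 (without lane set 4) for the interaction.

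In younger mice (12 against 12) the diet shifted lists of genes without a called member. Extracellular matrix genes (adjusted p = 3.24e-05), male-biased genes and acute phase genes (9.5e-05 each), stellate cell markers (0.0136) and mitochondrial check genes (0.0178) were lower with high vitamin D. Antigen presentation and xenobiotic genes (0.000442 each), fatty acid oxidation genes (0.00216), genes of cholesterol synthesis and uptake (0.00338), female-biased genes (0.00768) and pancreas markers (0.0136, median 1.98) were higher. None of these list calls held with an estimated correlation. There adjusted p = 0.475 for extracellular matrix, male-biased, acute phase, antigen presentation and female-biased genes, and 0.501 for xenobiotic genes. It was 0.734 for fatty acid oxidation genes and stellate markers, 0.737 for cholesterol genes and pancreas markers and 0.746 for mitochondrial genes. Over the list alone 2 xenobiotic genes rose.

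The response to age depended on the cross for 6 genes (4 and 2 in each direction; 1066 at the unadjusted threshold; 3 with the lane set as a block). DESeq2 called 40, of which 12 were higher and 28 lower. The values per cross below are differences of group means of log2(CPM + 0.5), and the interactions come from the fit. Spp1, which encodes osteopontin, differed with age by 0.30 in NODxPWK and 1.05 in PWKxNOD (interaction 0.82 ± 0.15, adjusted p = 0.0118). The tight junction gene Cgn differed by 0.16 and -0.39 (interaction -0.57 ± 0.10, adjusted p = 0.00627), the gap junction gene Gjb2 by -0.31 and 0.11 (0.42 ± 0.08, adjusted p = 0.0227) and the methyltransferase gene Smyd1 by -0.72 and 0.52 (1.34 ± 0.26, adjusted p = 0.0227). The response to the diet depended on the cross for 15 genes (52 by DESeq2), led by the monocarboxylate transporter gene Slc16a12 (-0.17 in NODxPWK and 0.59 in PWKxNOD; interaction 0.80 ± 0.15, adjusted p = 0.0274) and Nxpe2 (-0.10 and 0.52; 0.65 ± 0.12, adjusted p = 0.0274). The diet difference of Eif3d was 0.19 and -0.22 (-0.42 ± 0.09, adjusted p = 0.0393). Leaving out 1 lane set gave 0 to 8 genes for age by cross and 0 to 82 for diet by cross. A count of 0 in edgeR was reached without lane sets 3 and 5 for the former and without lane sets 4, 5 and 6 for the latter (788 to 1068 genes at the unadjusted threshold).

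The cross comparison sets PWKxNOD against NODxPWK mice, whose autosomes are alike and whose X, Y and mitochondrial genomes come from opposite strains. X-linked genes made up 8 of the 16 genes named for the largest differences. The glycerol kinase gene Gk (ENSMUSG00000025059, chromosome X, 85701937 to 85776819) was higher in PWKxNOD mice by 2.09 ± 0.07 (adjusted p = 3.37e-29). Alas2, the erythroid enzyme of heme synthesis (ENSMUSG00000025270, chromosome X, 150547375 to 150570638), was lower at -4.03 ± 0.09 (adjusted p = 8.44e-36), with 11.7 ± 3.97 CPM (SD, n = 24) in PWKxNOD and 193 ± 31.9 CPM in NODxPWK mice. Chic1 (-3.91 ± 0.15), the long noncoding RNA gene Firre (-3.55 ± 0.12), Mpp1 (-2.24 ± 0.08) and Rtl8b (-2.75 ± 0.26, 76.5% of windows shared) were lower, and Praf2 higher (2.45 ± 0.13, 33.5% shared). Of 348 X-linked genes 118 differed (33.9%), against 1149 of 11492 autosomal genes. Among 26 X-linked check genes 9 were higher and 5 lower (9 and 6 over the list alone), including Gla (1.34 ± 0.08) and Hprt (-1.34 ± 0.07). Of 15 mitochondrial check genes, mt-Nd5 (0.38 ± 0.07) and mt-Nd4l (1.78 ± 0.09) were higher and mt-Co2 lower (-0.36 ± 0.06). The last 2 had nearly all windows shared with other genes (98.7% and 99.5%), and the list was shifted up (adjusted p = 0.0223, adjusted p = 0.852 with an estimated correlation). On the Y chromosome Kdm5d was higher (0.24 ± 0.07) and Uty lower (-0.23 ± 0.07).

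Genes of the circadian clock were among the autosomal genes with large differences. Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), was lower in PWKxNOD mice at -1.94 ± 0.19 (adjusted p = 2.8e-10), and its relative Npas2 at -3.22 ± 0.36 (adjusted p = 4.55e-09). The repressor genes Per3 (1.53 ± 0.18) and Per2 (1.16 ± 0.14) and the clock-controlled genes Usp2 (2.45 ± 0.30) and Ciart (2.31 ± 0.31) were higher. The difference of Usp2 reversed with the clock score as a covariate, as did those of Per3 and Ciart, which are part of that score. Of 19 clock genes 11 were higher and 4 lower (11 and 5 over the list alone; list adjusted p = 0.000272, adjusted p = 0.0755 with an estimated correlation). Cdkn1a, a cell cycle inhibitor gene, was lower at -2.54 ± 0.33. Of 25 genes of cholesterol synthesis and uptake 13 were lower (17 over the list alone), with Hmgcs1 at -0.88 ± 0.17 and Pmvk at -0.76 ± 0.15. Cholesterol genes were lower as a list (adjusted p = 5.02e-08, adjusted p = 0.685 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was higher by 1.65 ± 0.28 (adjusted p = 3.17e-05). Of 21 bile acid genes 6 were higher and 2 lower (7 and 2 over the list alone; list adjusted p = 0.123). In fatty acid synthesis 2 genes were higher and 5 lower of 21 (2 and 9 over the list alone), with Thrsp at 0.79 ± 0.19 and Elovl5 at -0.54 ± 0.12. The shift of the list was down (adjusted p = 0.0421, adjusted p = 0.852 with an estimated correlation). Of 25 xenobiotic genes 3 were higher and 1 lower (4 and 1 over the list alone), with Alas1, the first enzyme of heme synthesis in liver, at 1.58 ± 0.29. Of 9 female-biased genes 3 were higher, among them Sult2a1 (2.78 ± 0.52), and Cyp2b9 was lower (-2.12 ± 0.33; 6 higher and 2 lower over the list alone). Of 19 male-biased genes 6 were higher and 1 lower (7 and 1 over the list alone), among them Elovl3 (-1.10 ± 0.15), with a list adjusted p = 0.0567 (0.0292 with the lane set as a block, adjusted p = 0.781 with an estimated correlation). With the clock score as a covariate the difference of Elovl3 was small and positive. The fibrinogen genes Fga (-0.30 ± 0.05), Fgg (-0.30 ± 0.05) and Fgb (-0.25 ± 0.05) were lower and the metallothionein gene Mt1 higher (1.46 ± 0.42) among 24 acute phase and metal response genes, of which 1 was higher and 4 lower, also over the list alone. The list of blood and erythroid genes passed the set test (adjusted p = 7.16e-16, and adjusted p = 0.00354 with an estimated correlation) through Alas2, the only called member of 5. Of 9 genes with known paternal expression 4 were lower (2 higher and 4 lower over the list alone; list adjusted p = 0.0133, adjusted p = 0.0755 with an estimated correlation).

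**Figure D4:**
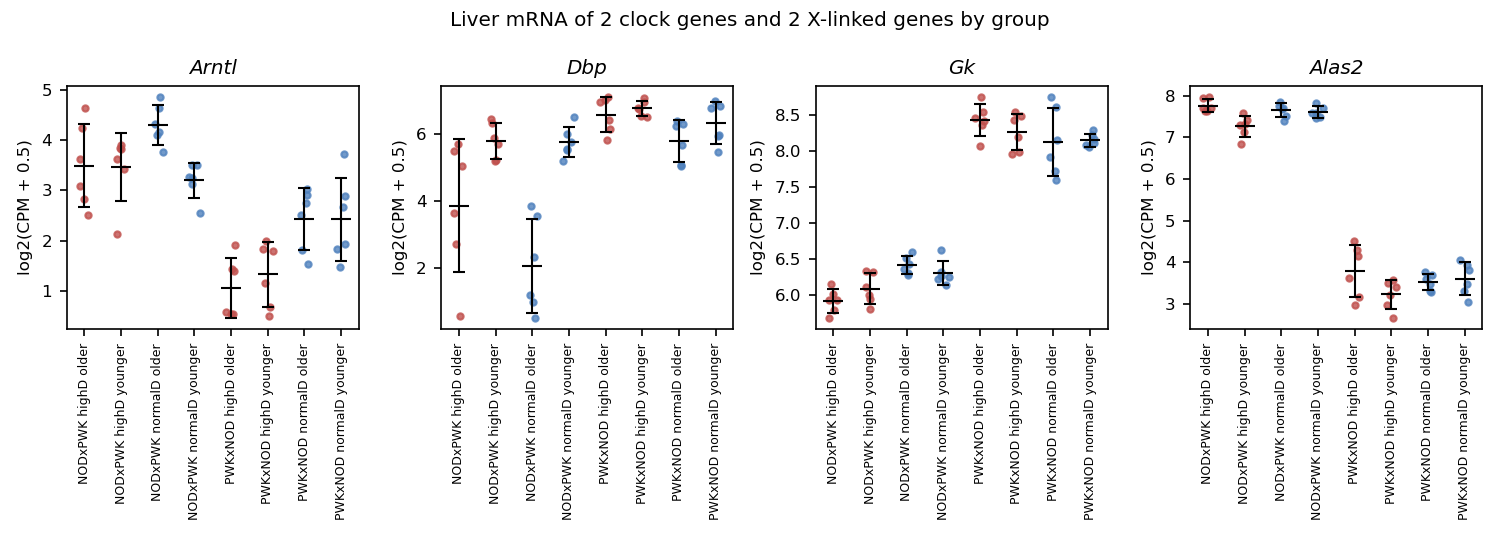
Expression of the clock genes Arntl and Dbp and the X-linked genes Gk and Alas2 as log2(CPM + 0.5) on the vertical axis in the 8 groups, with 1 point per mouse (red for high, blue for normal vitamin D), and bars at the mean and SD of 6 mice. PWKxNOD mice were lower in Arntl (-1.94) and Alas2 (-4.03) and higher in Gk (2.09).

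Transcripts of the exocrine pancreas also differed between crosses, through few mice. Of 13 markers 7 passed the test (13 over the list alone), with Amy2a5, an amylase gene, at 5.05 ± 1.31 (adjusted p = 0.00694), Pnlip, pancreatic lipase, at 4.19 ± 1.29, Cpb1 at 3.92 ± 1.22 and Cel at 3.52 ± 1.07. The list itself did not pass (median 3.86, adjusted p = 0.156). Pnliprp1, a pancreatic lipase relative, was higher by 2.57 ± 0.68. Of the 48 mice 10, 4 NODxPWK and 6 PWKxNOD, had a mean marker level above 1 on the log2 CPM scale. In 1 PWKxNOD mouse (high, younger, replicate 4) the markers held 0.199% of counts, against at most 0.0345% in any other mouse. Without lane set 4, which holds it, Amy2a5 stood at 4.43 and stayed called, and its call was lost without lane set 2 (3.15), 3 (3.33) or 5 (5.80). The calls of Pnlip, Cpb1 and Cel were lost without lane set 2, 3 or 4, and those of Pnlip and Cpb1 also without lane set 1 or 5. In total 1281 genes differed between crosses (642 higher, 639 lower in PWKxNOD; 1343 by DESeq2), and 62 with a clock score as a covariate.

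Allelic expression compares the PWK with the NOD copy of a gene within the same mouse. Of 9362 autosomal genes 4086 were unbalanced, 1956 towards PWK and 2130 towards NOD, and 862 of them at least 2-fold. The PWK allele held 47.2% ± 0.696 (SD, n = 48) of autosomal counts, and 5872 genes (62.7%) had a mean PWK share between 45 and 55%. Nearly all transcripts of the steroid dehydrogenase gene Akr1c18 (9.09 ± 0.44, adjusted p = 7.17e-12) and of the class I histocompatibility gene H2-Q2 (8.06 ± 0.23) were given to PWK, and those of Sdr9c7 (-8.76 ± 0.22) and Mea1 (-9.27 ± 0.39) to NOD. The remaining extremes mostly shared sequence with other genes, such as Mup18 (-16.1 ± 0.07, 87.6% of windows shared), Mup16 (-17.1 ± 0.01, 88.1%), Serpina1c (-10.4 ± 0.09, 75.3%), Rpl19 (10.5 ± 0.15, 52.6%), Cyp2c40 (8.39 ± 0.22, 49.4%) and the microRNA gene Mir6236 (9.85 ± 0.19), and their values depend on how reads were divided between copies.

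Unbalanced expression ran through the drug and bile acid genes of the liver. Of 22 xenobiotic genes 9 were higher from PWK and 12 from NOD (21 called over the list alone), with the carboxylesterase gene Ces2a at -2.89 ± 0.04, Cyp2b10 at -2.29 ± 0.04 and Gstp1 at -1.66 ± 0.02. Of 21 bile acid genes 7 were higher and 12 lower (19 over the list alone), including the sterol transporter gene Abcg5 (-1.64 ± 0.04) and Cyp7b1 (1.16 ± 0.04). In immune lists H2-K1, the class I heavy chain gene (-2.65 ± 0.05), and the immunity GTPase gene Iigp1 (-2.57 ± 0.04) leaned to NOD, and Xaf1 (3.24 ± 0.23) to PWK. Among 21 acute phase genes 8 were higher and 8 lower (16 over the list alone), with Hpx at 1.11 ± 0.02 and Itih3 at 1.06 ± 0.02. Of 17 glucose genes 11 were higher from PWK and 2 from NOD (13 over the list alone), among them Ldha (0.49 ± 0.02) and Pck1 (-0.51 ± 0.02). Genes of other cell types were unbalanced too, such as Spp1 (-0.89 ± 0.04) and the stellate cell gene Dcn (-0.76 ± 0.06). At a minimum mean count of 100 the number of unbalanced genes was 2684.

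Because males carry a single X chromosome, X-linked counts of the other strain were counts given to the wrong allele. They made up 4.95% ± 0.525 (SD, n = 48) of X-linked counts, 4.69% ± 0.31 in NODxPWK and 5.21% ± 0.572 in PWKxNOD mice (24 each), and a median of 0.061% over single genes. Some X-linked genes were split almost evenly between the strains, such as Vcp-rs (50%), Dynlt3 (50%), Tmsb4x (49.97%) and Ssr4 (48.1%). The pooled share is therefore not the error of a typical gene. For mitochondrial counts the share of the other strain was 8.83% ± 0.475. Both shares lay far below 50% in all mice (at most 6.6% and 9.67%), as the dam written first in each cross requires. The Y-linked counts were split evenly (PWK share 50.7% ± 1.16), although the Y chromosome comes from the sire alone, so the X-linked share does not measure the error for Y-linked genes. A PWK share near 50%, as in 62.7% of the tested autosomal genes, thus need not mean that both copies were equally expressed.

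Parent-of-origin effects were called for 25 of 9362 genes, 11 with higher maternal and 14 with higher paternal expression. Igf2r, the maternally expressed receptor that clears IGF2 (chromosome 17, 12682406 to 12769664), had 99.4% ± 1.11 of its allelic counts from the maternal copy (SD, n = 48; 99.2% in NODxPWK and 99.7% in PWKxNOD). Its log2 ratio was 7.86 ± 0.23 (adjusted p = 1.91e-27). Peg3 (1.72% ± 2.75 maternal), Zrsr1 (0.95% ± 3.05) and Impact (13.7% ± 12.1) were expressed from the paternal copy (log2 ratios -6.20 ± 0.29, -7.71 ± 0.41 and -2.99 ± 0.28). A maternal bias was partial for H13 (74.8% ± 7.73), Gnas (58.8% ± 5.29) and Slc22a18 (56.7% ± 6.39). Of the genes with known maternal expression 4 of 17 tested were called (5 over the list alone), and of those with known paternal expression 3 of 4 (3 over the list alone). Ddc (0.30 ± 0.10) was called only over the list alone. Cd81, Cobl, Ppp1r9a, Pon2 and Pon3, imprinted in other tissues, were not called in liver (log2 ratios 0.08 ± 0.11, 0.34 ± 0.30, -0.11 ± 0.14, 0.09 ± 0.08 and 0.05 ± 0.06).

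**Figure D5:**
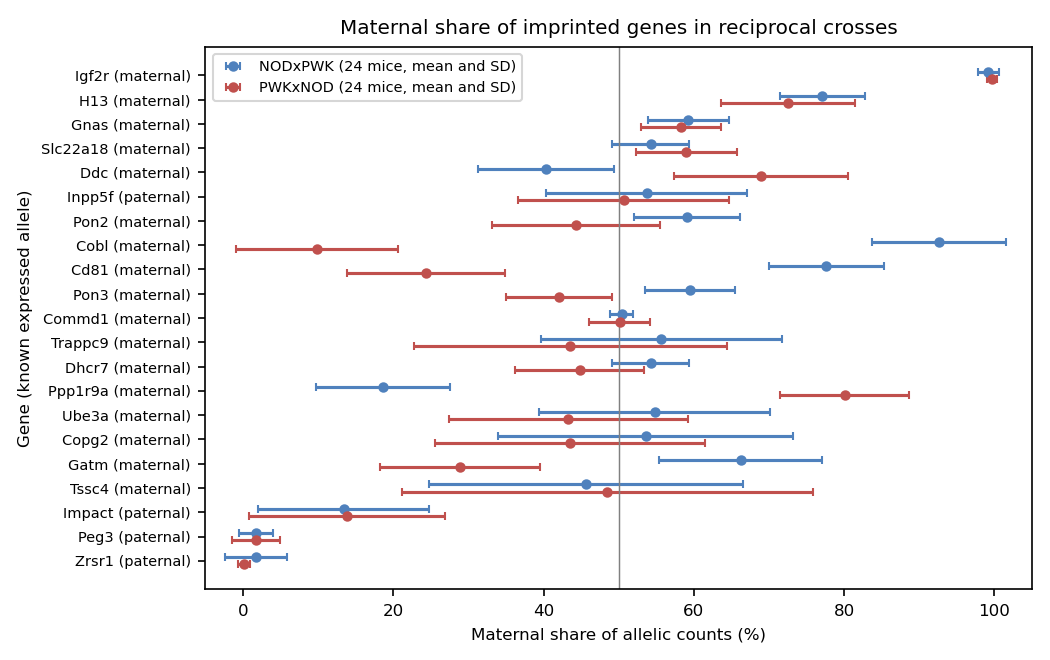
Maternal share of allelic counts in percent (horizontal axis) for 21 tested genes known to be imprinted, as mean and SD over 24 mice of each reciprocal cross. Igf2r lay at 99.4% and Peg3 and Zrsr1 at 1.72% and 0.95%, and Cobl at 92.7% in NODxPWK and 9.89% in PWKxNOD mice.

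Outside the imprinted lists, Dact2 had a maternal share of 97.5% ± 6.01 in NODxPWK and 42.3% ± 21.7 in PWKxNOD mice (log2 ratio 2.65 ± 0.33, adjusted p = 2e-06). Ctsz, cathepsin Z, averaged 53.3% maternal (0.20 ± 0.03), Depp1 56.0% (0.35 ± 0.07) and Ndrg1 55.5% (0.38 ± 0.09). Log2 ratios towards the paternal copy were found for Tmem176b (-0.24 ± 0.05), Upp2 (-0.22 ± 0.04), Txnip (-0.14 ± 0.03), Gpam (-0.12 ± 0.02) and Aldh1a1 (-0.11 ± 0.02). Except for Upp2 (42.9% and 49.6%), their maternal share lay on opposite sides of 50% in the 2 crosses, as for Aldh1a1 (68.1% in NODxPWK, 28.9% in PWKxNOD). A strain bias that differs in size between the crosses gives the same contrast and was not told apart from a parental effect. Between 16 (without lane set 6) and 23 (without lane set 5) genes were called when a lane set was left out.

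Age changed the allelic ratio of 66 genes, 34 towards PWK and 32 towards NOD in older mice, and 39 of them also differed with age in total expression. The PWK share of Haao, an enzyme of tryptophan breakdown, was 44.5% ± 4.52 in younger and 56.9% ± 3.55 in older mice (SD, n = 24 each; 0.72 ± 0.07, adjusted p = 3.8e-10). Saa1 moved from 42.04% to 58.8% (0.93 ± 0.13), Atp11a from 82.9% to 70.4% (-1.06 ± 0.11) and Cav1 from 92.6% to 83.6% (-1.34 ± 0.14). Ttr, transthyretin, moved from 50.2% to 46.3% (-0.23 ± 0.02) and Hamp, the iron hormone hepcidin, from 63.4% to 58.3% (-0.31 ± 0.04). The diet changed the ratio of 2 genes (436 at the unadjusted threshold). The PWK share of Gstt1, a glutathione transferase gene, was 52.4% ± 2.54 with normal and 48.3% ± 2.53 with high vitamin D (-0.24 ± 0.04, adjusted p = 0.00266). That of Serpina1a, with 51.5% of windows shared, was 75.3% ± 2.1 and 70.9% ± 3.39 (-0.32 ± 0.05, adjusted p = 0.0015). Leaving out a lane set gave 38 to 51 genes for age, with 38 without lane set 6 and 51 without lane set 4. For the diet edgeR called 0 (without lane sets 2 and 6; 391 and 408 at the unadjusted threshold) to 2.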

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

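The tests of clock genes, of the diet in older mice and of pancreas transcripts were chosen only after the results were seen, and the other splits of the mice were planned before. A mouse is listed here where it lay far from the other 5 mice of its group, or a gene where the difference between groups was itself tested.

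Clock genes and many other autosomal genes differed between the crosses. A constant effect of the cross on the log2 clock score is argued against by its 4 differences between PWKxNOD and NODxPWK mice. These were 3.63 (high, older), 2.22 (high, younger), 3.13 (normal, older) and 1.26 (normal, younger) and varied more than a constant effect gives (range 2.37, permutation p = 0.00839). The test takes the groups to vary alike, while their SDs ran from 0.448 to 1.703. It holds for the score on its log2 scale and does not test a constant shift of clock phase. A candidate explanation is that the mice of the 2 crosses were at different clock phases when sampled: over 19 clock genes, which are not independent replicates, the cross difference followed the within-group correlation with the score of the other clock genes (r = 0.837). With the score as a covariate the cross differences of 1134 other autosomal genes were a median of 0.415 times those without it, against 0.845 to 1.21 with permuted scores, while the ratio was 0.995 for 118 X-linked genes. The median size of these autosomal differences went from 0.29 to 0.13 and their median standard error from 0.07 to 0.12 (0.13 with permuted scores), so that the fall to 62 called genes (80 to 1076 with permuted scores, median 245.5) came with both smaller differences and larger errors. Time of sampling is not given in the labels, and a difference of the clock itself between the crosses stays open and untested.

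The diet called 445 genes in older mice and more than in any other comparison of diets here. That younger mice shared the older differences of these genes is argued against by a median ratio of 0.005 between the younger and older differences. The genes were chosen by their calls in older mice, so the ratio does not test a diet effect shared by both ages on other genes. Without the mice labelled 25 the median ratio to the differences of all older mice was 0.848, but this fit keeps 1 NODxPWK normal older mouse. The genes were called in a fit that also held the remaining mice, which can raise this ratio. It therefore does not decide whether the differences rested on the labelled mice. In 40 random removals of as many normal older mice per group the ratio was 0.817 to 1.21, with 2 draws as low. These draws are no control for the label. Of the 6 NODxPWK normal older mice 5 carry it, so each draw also took most of the labelled mice. A part played by the labelled mice stays open. Clock phase as the whole source is argued against by a ratio of 0.869 with the clock score (0.937 to 1.13 with permuted scores), although this lies below the permuted values, so that clock phase may carry a part (median size 0.39 without and 0.32 with the score, standard error 0.10 and 0.11, 53 called genes against 82 to 932). Without the mice with pancreas transcripts the ratio was 0.849, below all 30 random removals (0.87 to 1.12), with 18 called genes (7 to 431, median 149), and an effect of the diet that depends on age stays open.

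Exocrine pancreas transcripts appeared in 10 of 48 mice. Among older mice these were NODxPWK normal replicates 1, 2 and 5, PWKxNOD normal replicates 2 and 3, NODxPWK high replicate 6 and PWKxNOD high replicate 2. They were thus uneven between the diets in older mice. Pancreatic tissue carried into the sample of some mice is a candidate explanation: the 13 markers rose and fell together within groups (median pairwise correlation 0.974, lowest 0.74), reached 0.199% of counts, and in the mouse with the highest level (mean log2 CPM 6.95) stood far above the other mice of its lane set (at most 0.3). Whether the 2 crosses differ in how many mice carry these transcripts cannot be told apart from chance with 4 and 6 of 24 mice (Fisher exact p = 0.724). A source of these transcripts within the liver was not tested.

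Single mice far from their groups were PWKxNOD normal older replicate 1 in summed counts (2.03 M, in mega counts, others 4.97 to 6.25). In X-linked counts given to the other strain they were PWKxNOD high older replicate 5 (6.35%, others 4.64 to 5.05) and PWKxNOD normal younger replicate 4 (6.6%, others 4.55 to 5.1). In mean log2 CPM of pancreas markers they were NODxPWK high older replicate 6 (2.44), NODxPWK high younger replicate 5 (0.261), PWKxNOD high older replicate 2 (3.36) and PWKxNOD normal younger replicate 3 (4.03). In haemoglobin genes it was NODxPWK high younger replicate 1 (3.51, others 5.94 to 6.78). These are 8 of 64 groups over 8 measures, and among 219 named genes 117 of 1752 gene and group pairs (6.68%) held such a mouse, where chance gives about 5%. Counts outside the annotation used here made up 0.16% of the total.

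Differences of an effect between groups were called for 74 genes (diet by age), 6 genes (age by cross) and 15 genes (diet by cross). The diet effect differed with age by 0.84 for Cyp4v3 (-0.35 in younger, 0.49 in older mice, from the same fit), 1.245 for Gnat1 (-0.19, 1.06), -1.85 for Cyp2b10 (1.02, -0.83) and 0.83 for Scmh1 (-0.52, 0.31). The age effect differed between crosses by -0.57 for Cgn, 0.82 for Spp1, 1.34 for Smyd1 and 0.42 for Gjb2, and the diet effect by 0.65 for Nxpe2, 0.80 for Slc16a12 and -0.42 for Eif3d.

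The mice were split 100 times into groups of the same sizes, the real split included. Only the real split, 1 of 100, called as many genes for age (1439 genes, highest other split 1) and cross (1281, highest 1). So it was for the diet in older mice (445, highest 141) and diet by age (74, highest 3). A share of 1 of 100 is the smallest these splits can give, so it argues against chance without excluding it. The allele splits were fitted with limma on log2 ratios, and there the same held for allele (4196 genes in the real split, highest 1), parent of origin (25, highest 1) and age on the allele ratio (68, highest 1). For the diet (41 genes, highest 169), age by cross (6, highest 68), diet by cross (15, highest 131) and the diet on the allele ratio (2, highest 2), 2 of 100 splits called as many. This is under the planned 0.05 but was not adjusted over the results, so it argues against chance without excluding it. For the diet, age by cross and diet by cross the 1 other split called several times the real count, which points to a structure of the samples other than the groups, and which one was not tested on these splits. For interactions, diet by age included, the splits permuted age or diet and so removed its main effect too. They do not test the interaction alone. For the diet in younger mice the splits say nothing about chance, since edgeR called 0 genes (573 at an unadjusted p of 0.05, 10 by DESeq2) and all 100 splits necessarily called as many (highest 1).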

How the results depend on the processing

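The fits without the mice of the shallowest barcode, without the mice with pancreas transcripts, and with a clock or haemoglobin score were chosen only after the data were seen; the other alternatives were planned. RLE scaling, counts not rounded, a mean CPM of at least 1, a haemoglobin score, limma on allele ratios, other scaling of alleles and filterByExpr alone left each count of called genes within 1.5 times. The lane set as a block gave 3 genes for age by cross, and list adjusted p of 0.0485 (age, male-biased), 0.0292 (cross, male-biased) and 0.0392 (diet in older mice, stellate markers). It took the matrix list for diet by age from 0.0492 to 0.0652, and 9 of 233 results of named genes on total expression and 2 of 135 on alleles lost their call. Of 368 results of named genes 328 were past the threshold, 171 of them in every setting, and 150 lost it in at least 1 setting with the sign kept. Reversals of sign were counted apart, and a result can be in both counts. Of the 368 results 15 reversed in at least 1 setting, 5 of them genes by which the setting itself was defined. Single flowcells were not run, since the files hold 1 column per mouse. Depth of 2.03 to 7.48 M (mega) limits genes of low expression. Except where fewer mice or genes were tested, the cause was not tested.

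DESeq2 called 111 genes for the diet, 158 for diet by age, 40 for age by cross (12 higher and 28 lower, against 4 and 2), 52 for diet by cross and 10 for the diet in younger mice. Without a count filter edgeR called 24 for the diet, 23 for diet by age, 2 for diet by cross and 290 for the diet in older mice. Without the mice of the shallowest barcode it called 16 for the diet, 39 for diet by age and 2 for age by cross. At a mean count of 100, 2684 genes were unbalanced between alleles, and the X-linked share was 4.11%, or 0.061% as a median over genes.

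Without the 7 mice labelled 25, which leaves 1 NODxPWK normal older mouse that is assumed to vary like the other groups, edgeR called 778 genes for age (661 shared), 0 for the diet (976 at an unadjusted p of 0.05), 0 for diet by age (1033), 4 for diet by cross, 3 for the diet in younger and 6 in older mice (5 shared), and Lcn2 stood at -0.50 for age. Without the 10 mice with pancreas transcripts it called 904 for age (849 shared), 0 for the diet (1029), 0 for diet by age (857), 0 for diet by cross (1837) and 18 for the diet in older mice (17 shared), and for cross Amy2a5 stood at -0.49, Pnlip at -0.076 and Cpb1 at -1.05, which says nothing about them since the mice were chosen by these markers. With the clock score it called 740 for age (655 shared), 0 for the diet (849), 62 for cross (60 shared), 11 for diet by age, 0 for diet by cross (1417) and 53 for the diet in older mice (52 shared). The cross differences that reversed with it were those of Usp2 (-0.33), Ciart (-0.50), Dgat2 (-0.034), Pdk4 (0.47), Per3 (-0.087), Elovl3 (0.033), Pck1 (-0.13), Pfkfb3 (-0.17), Sds (-0.066), Stat5b (0.082) and Sox9 (0.001). Ciart and Per3 are part of the score, so their change follows from the adjustment.

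With an estimated correlation acute phase genes and cholangiocyte markers for age, erythroid genes for cross and male-biased genes for diet by age stayed past the threshold, and the other list calls did not. Adjusted p was then, for age, 0.501 (cholesterol), 0.233 (fatty acid synthesis), 0.172 (fatty acid oxidation), 0.0997 (clock), 0.0592 (female-biased), 0.0933 (xenobiotic, glucose), 0.526 (matrix) and 0.2 (stress). For the diet it was 0.805 (fatty acid oxidation) and 0.731 (male-biased, glucose, antigen presentation, matrix, stellate). For cross it was 0.685 (cholesterol), 0.852 (fatty acid synthesis, mitochondrial) and 0.0755 (clock, paternally expressed), and for the diet in older mice 0.507 (fatty acid oxidation, xenobiotic, glucose, stress), 0.164 (male-biased) and 0.836 (mitochondrial).

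With each lane set left out in turn, counts ranged from 1042 to 1403 for age, 6 (without lane set 3) to 43 for the diet, 872 to 1167 for cross, 4 (without lane set 1) to 88 for diet by age, 0 (without lane set 3 and 5; 983 and 788 at an unadjusted p of 0.05) to 8 for age by cross, 0 (without lane sets 4, 5 and 6; 1052, 962 and 1068) to 82 (without lane set 2) for diet by cross, 171 (without lane set 6) to 439 for the diet in older mice, and 0 to 0 in younger mice (410 to 630). For alleles they ranged from 3783 to 3881 (PWK over NOD), 16 (without lane set 6) to 23 (parent of origin), 38 (without lane set 6) to 51 (age) and 0 (without lane sets 2 and 6; 391 and 408) to 2 (diet).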

Other observations

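The tests below were chosen only after the results were seen. Stellate cell markers varied between mice of the same group in the opposite direction to haemoglobin transcripts. Over 48 mice, as deviations from group means, the mean of 12 stellate markers had a Pearson r of -0.881 and a Spearman rho of -0.89 with the mean of the haemoglobin genes (permutation p = 1e-05 each, the smallest that 100000 permutations give, adjusted over 4 relations 1.3e-05). The r was -0.864 without the 2 farthest mice, -0.916 within NODxPWK and -0.836 within PWKxNOD, and all 12 genes were negative, among them Dcn (-0.897), Colec11 (-0.87) and Ecm1 (-0.853). Extracellular matrix genes had an r of -0.8 and a rho of -0.824 (-0.766 without the 2 farthest mice, -0.847 and -0.732 within crosses, 18 of 19 genes negative). Endothelial markers went the other way (r = 0.601, rho = 0.641, 0.582 without the 2 farthest mice, 0.764 and 0.483 within crosses), as did Kupffer cell markers (r = 0.463, p = 0.00087, rho = 0.42, p = 0.0033, 0.401 without the 2 farthest mice, 0.429 and 0.554 within crosses). Dilution of the sample by blood RNA is argued against as a source, since haemoglobin genes held at most 0.0754% of counts. The haemoglobin genes share sequence, so that their single values are uncertain.

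Genes with a parent-of-origin effect outside the imprinted lists lay near imprinted genes more often than random genes. Of 18 such genes 4 lay within 2 Mb of a listed gene, against a mean of 0.794 over 10000 random draws (p = 0.0059): among them Ctsz, 80.7 kb from Gnas; Gm38393, 662.6 kb from Ube3a; and Dact2, 1334.9 kb from Airn. Gm38393 was expressed from the paternal copy (log2 ratio -8.79 ± 0.44). Its maternal share was 0% in NODxPWK and 0.64% in PWKxNOD mice, which argues against a strain bias as the source for this gene. Ube3a was not called in liver (-0.06 ± 0.16), which does not count against the parental effect of Gm38393. Whether the others of these 4 genes belong to imprinted regions stays open. The other 14 genes lay farther away or on a chromosome without a listed gene.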
